A study of Mus musculus with 13 samples.

How the data were processed

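Small RNA was measured in 13 libraries from mouse material: 3 of vesicles (TMVs) from medium conditioned by C26 cells for 48 h, 6 of plasma vesicles from C26-bearing mice on day 14 and 4 of plasma vesicles from control mice. Per the labels' protocols, vesicles were collected by successive spins ending at 100 × 1000 g, RNA was isolated with TriPure, libraries were made with a small RNA kit and read as 75 bp single reads on a NextSeq500. The submitters' processing notes name bcl2fastq and cutadapt 1.10. The aligner, the counting tool, the miRNA annotation and the genome build are not given in the sources used here. The deposited values are raw counts per mature miRNA, whole numbers that sum to a different total in each library, and the authors gave them in 2 tables, one of 1164 miRNAs for TMVs and one of 1354 for plasma, with 1066 in both. No count was above 0 in any library for 497 miRNAs of the TMV table and 399 of the plasma table. How counts of near-identical miRNAs were shared is not given in the sources used here, so members of the let-7 family and other close families are uncertain against each other.

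Groups and replicate numbers come from the sample titles. The descriptions of control replicates 2 and 3 carry 2 numbers each, and the meaning of these is not stated. The plasma descriptions also carry sheet numbers 15 to 24. Nothing states that each library came from a separate animal, so the p-values measure the spread between these libraries. Replicate numbers were not treated as pairs.

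The plasma comparison used edgeR 4.0.16 in R 4.3.3: counts were filtered with filterByExpr by group (minimum count 10), which kept 130 miRNAs, scaled with TMM factors, and tested with the robust quasi-likelihood fit and Benjamini-Hochberg adjustment at 0.05. Levels are TMM-scaled CPM computed from the deposited counts, and log2 fold changes are C26-bearing minus control. Gene lists were tested with camera in limma 3.58.1 with an inter-gene correlation of 0.01, two-sided, adjusted over the 12 lists with at least 3 members tested. The 14 lists covered muscle, red cell, liver, platelet and endothelial, myeloid and inflammation-induced, lymphocyte, epithelial and other-tissue miRNAs, the miR-17/92 and Dlk1-Dio3 clusters, the let-7 and miR-34 families, energy metabolism and hypoxia miRNAs and muscle-wasting-linked miRNAs. The 50 miRNAs with the highest mean CPM in TMVs that were also in the plasma test formed 1 more set. Values of single libraries were compared between groups with exact permutation tests, two-sided, over the 210 splits of 10 libraries into 6 and 4, where the smallest possible p is 0.00476. The haemolysis index added 0.5 to each count. The TMV profile gives shares of counts with no test. The groups, lists, tests of the comparisons and most alternatives were chosen before the data were examined. The alternatives on miR-5119 and shallow libraries and the tests of explanations were chosen afterwards.

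Depth ran from 7962 to 131385 counts in plasma, a 16.5-fold range, and from 112357 to 170571 in TMVs. A count of 0, taken as up to 3 counts, allows up to 377 CPM in the shallowest plasma library and 22.8 CPM in the deepest. Intervals and such floors cover counting error only, since reads without molecular identifiers are not independent molecules. The plasma test was tested on simulated data with the means and library sizes of these libraries, 30 of 130 miRNAs changed in each of 20 runs, and 1.44% of calls were false. Each miRNA was drawn independently, so these data hold no structure shared between miRNAs. The rate of false calls may not apply to libraries that share such structure.

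The miRNAs named for the plasma comparison follow a rule: because fewer than 10 passed, the 10 with the smallest p, the 6 most abundant in control plasma, up to 4 of smallest p in each list and the 10 most abundant TMV miRNAs in the plasma test, 52 in all. The 15 most abundant are named for TMVs. The positions of precursors were taken from the GENCODE M21 annotation of GRCm38 by precursor name, and the build used by the authors is not given in the sources used here.

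Alternatives planned were RLE, upper quartile and total-count scaling, no filter and a filter of 10 CPM in 4 libraries, DESeq2 1.42.0, limma voom with quality weights, a fit without robust estimation, a block on replicate number, each library left out in turn, both controls with 2 numbers left out, camera with an estimated correlation, fry, other set sizes, other detection minimums and other haemolysis ratios. Alternatives for normalised values or several RNA classes did not apply. Chosen after seeing the data were leaving miR-5119 out of the table, a term for libraries with over 20% miR-5119, each of these parts alone, and leaving out the 2 plasma libraries under 10000 counts. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the other steps.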

Results

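Small RNAs carried by extracellular vesicles were sequenced from 2 materials in a mouse model of cancer cachexia, the wasting of muscle and body mass that accompanies some tumours. C26 cells are a colon adenocarcinoma line derived from Balb/C mice. Vesicles released by cultured C26 cells into serum-free medium over 48 h, called tumour microvesicles (TMVs) here, gave 3 libraries. Vesicles pelleted from plasma gave 6 libraries from mice killed on day 14 after subcutaneous injection of C26 cells and 4 libraries from control mice. The values are raw counts per mature microRNA (miRNA). The TMV libraries held between 112357 and 170571 counts. The plasma libraries were shallower and more uneven, with 19298, 76376, 66088, 9828, 27846 and 32234 counts in C26-bearing replicates 1 to 6 and 126010, 55769, 131385 and 7962 counts in control replicates 1 to 4. Total counts were 38611.7 ± 26605.2 (SD, n = 6) in C26-bearing mice and 80281.5 ± 59255.5 (SD, n = 4) in controls, and the difference did not pass an exact permutation test (two-sided p = 0.171, adjusted over 4 library measures 0.371). The number of miRNAs with at least 1 count was 367.5 ± 113.0 in C26-bearing mice and 317.0 ± 38.1 in controls (exact permutation p = 0.414, adjusted 0.414).

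**Figure D1:**
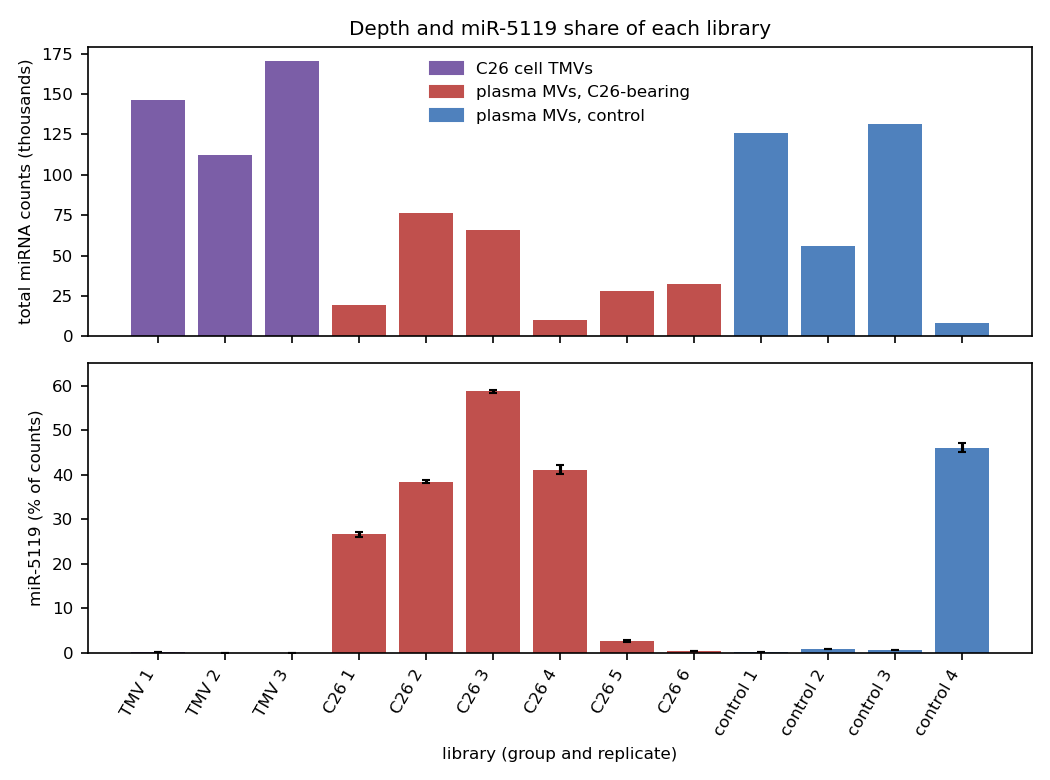
Total miRNA counts (upper panel, in units of 1000) and the share of counts taken by miR-5119 (lower panel, percent, with 95% Wilson intervals) in each of the 13 libraries, coloured by group. Control replicate 4 and C26-bearing replicates 1 to 4 each hold over 20% miR-5119, and the other plasma libraries hold between 0.0968% and 2.55%.

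The plasma libraries fell into 2 parts that crossed the groups. miR-5119 held 26.6%, 38.4%, 58.7% and 41.1% of the counts in C26-bearing replicates 1 to 4 and 46.1% in control replicate 4. It held 2.55% and 0.332% in C26-bearing replicates 5 and 6, and 0.0968%, 0.819% and 0.641% in control replicates 1 to 3. The 95% Wilson intervals of these shares, which cover counting error only, ran from 25.9% to 27.2% at the lowest of the 5 high libraries and from 2.37% to 2.74% at the highest of the 5 low ones. The 5 libraries rich in miR-5119 have the consecutive sheet numbers 18 to 22 among the plasma numbers 15 to 24. The first principal component of log2 CPM (counts scaled to a common library size) held 52.4% of the variance and separated these 5 libraries from the other 5. The difference in miR-5119 share between C26-bearing and control mice did not pass an exact permutation test (p = 0.352). The annotated precursor of miR-5119 lies in an intron of Cdk12 on chromosome 11, from 98262606 to 98262662 on the plus strand of GRCm38. Of its 18-base words none occurred in another gene among 141767 annotated transcripts, whose 22 tRNAs are mitochondrial. Nuclear tRNAs and unannotated RNA were not searched, so the RNA behind these counts is not established. In the TMV libraries miR-5119 held 0.0200% ± 0.0158 (SD, n = 3) of the counts.

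The first aim of the design was a profile of the small RNAs in TMVs. The let-7 family, miRNAs that repress growth-promoting genes in differentiated cells, held 26.6% ± 0.721 (SD, n = 3) of all TMV counts. Its most abundant member was let-7i-5p with 8.14% ± 1.10, followed by let-7c-5p with 6.37% ± 0.895, let-7f-5p with 3.79% ± 0.126, let-7b-5p with 3.64% ± 0.607 and let-7g-5p with 2.48% ± 0.142. These members differ by few bases, so counts can be shared among them. miR-21a-5p, which is abundant in many tumours, held 7.90% ± 1.72. miR-140-3p held 4.26% ± 0.554, miR-143-3p 4.21% ± 0.745, miR-148a-3p 4.06% ± 0.758, miR-378a-3p 3.34% ± 0.464 and miR-99b-5p 3.26% ± 0.676. miR-30d-5p held 3.08% ± 0.388, miR-26a-5p 2.70% ± 0.373, miR-125b-5p 2.67% ± 0.522 and miR-24-3p 1.96% ± 0.280. Together these 15 miRNAs held 61.9% ± 1.89 of the counts. At least 10 counts in each of the 3 libraries were found for 167 miRNAs.

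**Figure D2:**
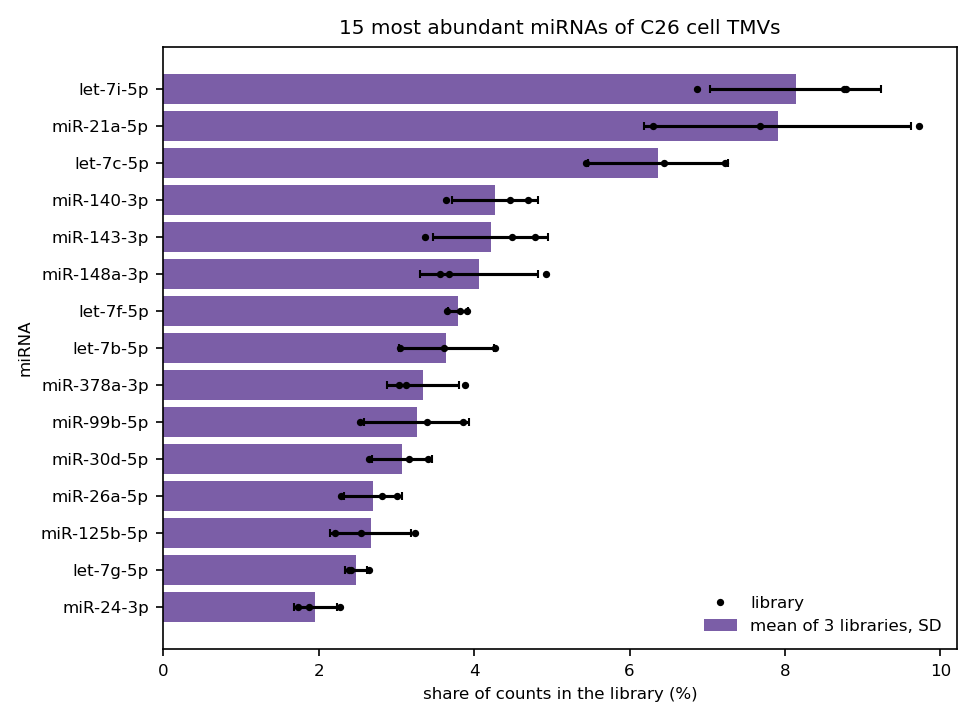
Share of counts (percent) of the 15 most abundant miRNAs in C26 cell TMVs. Bars are means of 3 libraries, error bars are SDs and points are single libraries. let-7i-5p and miR-21a-5p lead with means of 8.14% and 7.90%, and their points overlap.

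The precursors of the leading TMV miRNAs were located in the GRCm38 annotation. Mirlet7i lies on chromosome 10 from 122985640 to 122985724 on the minus strand, in an exon of the transcript D630033A02Rik. Mir21a lies on chromosome 11 from 86584067 to 86584158 on the minus strand, in an exon of Vmp1. Mir140 lies in an exon of Wwp2 on chromosome 8, from 107551244 to 107551313 on the plus strand. Mir378a lies in an intron of Ppargc1b on chromosome 18, from 61397835 to 61397900 on the minus strand. Mature let-7c-5p can come from 2 precursors, Mirlet7c-1 on chromosome 16 and Mirlet7c-2 on chromosome 15, which these counts do not separate.

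After let-7, 3 of the lists of tissue and function held the next largest shares of TMV counts. The 12 listed myeloid and inflammation-induced miRNAs held 9.21% ± 1.71 (SD, n = 3) of TMV counts, most of it miR-21a-5p. The muscle-wasting-linked list held 10.5% ± 2.06, and miR-21a-5p belongs to that list as well. The energy metabolism and hypoxia list held 9.16% ± 1.02, the platelet and endothelial list 6.17% ± 0.856, the list of pancreas, gut and neural miRNAs 5.36% ± 0.786 and the miR-17/92 cluster with its paralogues 1.49% ± 0.208. The epithelial list held 0.623% ± 0.156, the lymphocyte list 0.216% ± 0.0457, the miR-34 family induced by p53 0.253% ± 0.0433, the liver list 0.157% ± 0.0499 and the imprinted Dlk1-Dio3 cluster 0.0135% ± 0.00874. The erythrocyte list held 0.850% ± 0.609 and the muscle-enriched list 0.489% ± 0.524, each with an SD near its mean.

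TMVs and plasma vesicles were prepared and counted in separate tables, and sheet numbers 22 to 24 occur in both materials, so a difference between them cannot be separated from a difference between runs. Of the 50 most abundant miRNAs in TMVs, 32 were among the 50 most abundant in control plasma and 30 among those in C26-bearing plasma. Random draws from all 1066 miRNAs in both tables would share 2.35. Those 1066 include miRNAs without any count, so 2.35 understates the overlap expected among detected miRNAs. The overlap therefore does not show a link between the 2 materials. The let-7 family held 6.06% ± 0.812 (SD, n = 6) of the counts in C26-bearing plasma and 4.73% ± 1.35 (SD, n = 4) in control plasma, against 26.6% in TMVs. Without miR-5119 in the totals its share was 9.31% ± 3.83 in C26-bearing plasma and 5.62% ± 1.83 in control plasma. The most abundant miRNAs of control plasma were miR-486a-5p with 16.1% ± 9.92, found in red cells, the liver miRNA miR-122-5p with 15.9% ± 10.7, miR-5119 with 11.9% ± 22.8, miR-148a-3p with 11% ± 2.00, the red cell miRNA miR-451a with 3.72% ± 1.38 and miR-99a-5p with 2.39% ± 1.42.

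The second aim was to compare plasma vesicles of C26-bearing and control mice. The difference with the smallest p was in miR-455-5p, whose precursor lies in an intron of the collagen gene Col27a1 on chromosome 4, from 63256851 to 63256932 on the plus strand. Its level was 68.3 ± 58.0 TMM-scaled CPM (SD, n = 6) in C26-bearing mice and 1124 ± 383 (SD, n = 4) in controls, a log2 fold change of -4.04 (SE 0.872), and all 6 C26-bearing libraries lay below all 4 controls. The raw counts were 2, 11, 0, 1, 2 and 0 in C26-bearing replicates 1 to 6 and 172, 89, 163 and 4 in control replicates 1 to 4. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over 130 miRNAs the adjusted p was 0.0809, so miR-455-5p did not pass 0.05. It passed when C26-bearing replicate 2 was left out (edgeR adjusted p = 0.0461) and when replicate 3 was left out (0.0338). It also passed with a term for the miR-5119 part of each library (log2 fold change -4.38, edgeR adjusted p = 0.0386). Without a filter on low counts the edgeR adjusted p was 0.0213. DESeq2 (adjusted p = 9.52e-06) and limma voom with quality weights (adjusted p = 0.00645) called miR-455-5p too. The edgeR adjusted p was 0.264 without control replicate 1 and without control replicate 2, 0.191 without control replicate 3, 0.164 with a replicate block and 0.998 without both controls that carry 2 numbers, and the log2 fold change lay between -4.59 and -3.66 with each library left out. Within the 5 libraries with little miR-5119 the log2 fold change was -5.19 (SE 1.03, edgeR adjusted p = 0.0902) and within the 5 with much, which hold 1 control that is assumed to vary like the others, it was -2.98 (SE 1.93).

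Across all 130 miRNAs tested, 0 passed an adjusted p of 0.05 with edgeR, while 15 had an unadjusted p under 0.05, 9 of them higher and 6 lower in C26-bearing mice. This unadjusted count rested on single libraries. It was 30 (25 higher, 5 lower) without control replicate 4, 23 (13 higher, 10 lower) without C26-bearing replicate 6, 9 (5 higher, 4 lower) without C26-bearing replicate 3, 9 (3 higher, 6 lower) without control replicate 1 and also without control replicate 3, and 8 (3 higher, 5 lower) without control replicate 2. It was 1 without both controls that carry 2 numbers. DESeq2 called 4 miRNAs on the same counts (miR-455-5p, miR-375-3p, miR-8101 and miR-21a-5p), and limma voom with sample quality weights called 17, 7 higher and 10 lower. Among the 17 were miR-5119 (log2 fold change 5.02, against 1.05 with edgeR) and miR-5106 (5.16). The level of miR-5106 was 13.4 to 15.9 log2 CPM in the libraries with much miR-5119 and 7.13 to 10.7 in the others. Some of the voom calls therefore cannot be separated from the miR-5119 parts. Without a filter on low counts edgeR called 4 among 955. Within the libraries with little miR-5119 edgeR called 0, and with the part as a term 2 (miR-455-5p and miR-146a-5p). Within those with much it called 1 (miR-7082-5p, named after its value was seen), which rests on the single control of that part, where it held 1.63% of counts. The biological coefficient of variation was 0.896. On simulated data of this size and spread, 5% of 2-fold, 23% of 4-fold and 74.5% of 16-fold changes were called. The simulated miRNAs were drawn independently, without the miR-5119 parts of the real libraries, so these rates may not hold here.

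Among miRNAs that C26 cells release in quantity, miR-21a-5p and let-7a-5p had the clearest separation, with no call in edgeR. DESeq2 called miR-21a-5p (adjusted p = 0.0278). With limma voom and quality weights, miR-21a-5p (adjusted p = 0.0269) and let-7f-5p (adjusted p = 0.0320) were called. miR-21a-5p stood at 25596 ± 11583 TMM-scaled CPM in C26-bearing mice and 9944 ± 3393 in controls (log2 fold change 1.37, SE 0.438), and 5 of 6 C26-bearing libraries lay above all 4 controls. let-7a-5p stood at 7288 ± 3222 and 3548 ± 698 (1.04, SE 0.407), with 6 of 6 above all controls. let-7f-5p had a log2 fold change of 1.30 (SE 0.502) and let-7i-5p of 0.62 (SE 0.371). The edgeR adjusted p was 0.304 for miR-21a-5p, 0.395 for let-7a-5p and let-7f-5p, and 0.609 for let-7i-5p. Within the libraries with little miR-5119 the log2 fold change was 0.86 (SE 0.450) for miR-21a-5p and 1.34 (SE 0.533) for let-7a-5p, and within those with much it was 1.03 (SE 0.719) and 0.58 (SE 0.601). The log2 fold changes of other leading TMV miRNAs lay within 2 SE of 0, with let-7c-5p at -0.27 (SE 0.398), let-7b-5p at -0.60 (SE 0.720), miR-140-3p at -0.17 (SE 0.604), miR-143-3p at 0.00 (SE 0.552), miR-148a-3p at -0.71 (SE 0.509), miR-378a-3p at -0.03 (SE 0.388) and miR-99b-5p at -0.09 (SE 0.662).

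As a set, the 50 most abundant TMV miRNAs did not differ from the other miRNAs between the plasma groups. With camera the direction was up with p = 0.458, and p was 0.469 with an estimated correlation. The median log2 fold change was -0.03 and the mean 0.10, so they differ in sign; 23 members lay above 0 and 27 below. The camera p of the set, in a model across all miRNAs, was 0.0478 with the direction up when C26-bearing replicate 3 was left out. It was 0.0402, also up, with the 100 most abundant miRNAs in place of 50, which leaves few of the 130 tested to compare with. When C26-bearing replicate 6 was left out, the direction turned down and the camera p was 0.865. The camera p was 0.144 within the libraries with little miR-5119, and 0.0733 within those with much, which hold 1 control.

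**Figure D3:**
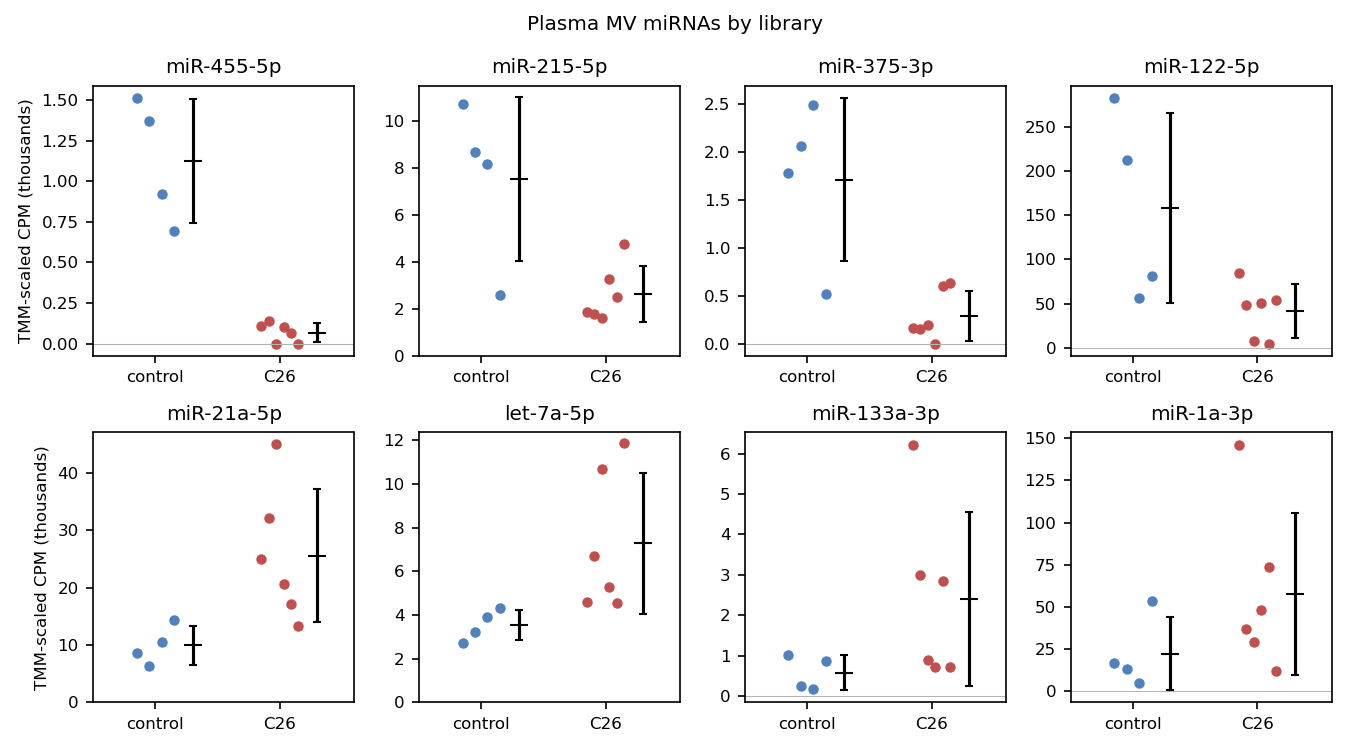
TMM-scaled CPM (in units of 1000, linear axes that differ between panels) of 8 miRNAs in plasma vesicles. Points are libraries, 4 control and 6 C26-bearing, and the bars beside them are the mean and SD. For miR-455-5p all 6 C26-bearing libraries lie below all controls and for let-7a-5p all 6 lie above, while the other panels overlap. No miRNA passed the adjusted test in edgeR.

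The epithelial list was lower in C26-bearing plasma with camera (adjusted p over 12 lists 0.0243), the only list past 0.05 in that test. The call was lost with an estimated correlation (adjusted p = 0.383) and with fry (adjusted p = 0.0636). Of the 10 listed, 5 were tested, with a median log2 fold change of -1.09, and 4 of 5 lay below 0. miR-215-5p, found in intestine, had a log2 fold change of -1.52 (SE 0.465), miR-375-3p, found in pancreatic islets and gut, -2.54 (SE 0.781), miR-200a-3p -1.09 (SE 0.512) and miR-205-5p -0.46 (SE 0.621). Adjusted over the list alone 2 members passed with edgeR, miR-215-5p and miR-375-3p, against 0 over all miRNAs with edgeR. Over all miRNAs DESeq2 called miR-375-3p (adjusted p = 0.0129). There limma voom with quality weights called miR-375-3p (adjusted p = 0.00645) and miR-215-5p (adjusted p = 0.0269). The camera adjusted p of the list was 0.127, 0.107, 0.0927, 0.156 and 0.213 without C26-bearing replicates 1, 2, 4, 5 and 6 in turn and 0.115 without control replicate 4. It was 0.441 within the libraries with little miR-5119 and 0.0737 with the part as a term. Within the libraries with much miR-5119 the list had too few members tested. In TMVs, miR-215-5p had 0, 1 and 0 counts and miR-375-3p 0, 0 and 1.

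Muscle-enriched miRNAs had higher mean levels and liver miRNAs lower mean levels in C26-bearing plasma, without passing as lists. All 3 muscle miRNAs tested had a log2 fold change above 0: miR-133a-3p 2.09 (SE 0.855), miR-206-3p 2.60 (SE 1.15) and miR-1a-3p 1.38 (SE 0.806). Single libraries moved these values, miR-206-3p to 1.24 without C26-bearing replicate 6, which held 210 of its counts, and miR-1a-3p to 0.83 without C26-bearing replicate 1 and 2.52 without control replicate 4. With a replicate block miR-206-3p had 0.77. The list median was 2.09 (camera adjusted p = 0.0656; adjusted p = 0.383 with an estimated correlation). Of the 4 liver miRNAs tested 3 lay below 0: miR-122-5p -1.92 (SE 0.820), miR-192-5p -0.98 (SE 0.604) and miR-194-5p -0.90 (SE 0.589), while miR-101b-3p had 0.80 (SE 0.751). The list median was -0.94 (camera adjusted p = 0.137). miR-122-5p stood at 41783 ± 30482 TMM-scaled CPM in C26-bearing mice and 158043 ± 107745 in controls, below all controls in 5 of 6 C26-bearing libraries. Within the libraries with little miR-5119 the adjusted p was 0.00634 for the muscle list and 0.0122 for the liver list, and with the part as a term it was 0.0259 for both. Those with much hold 1 control, so their values of 0.867 and 0.935 do not show that a difference is absent. The muscle list also passed without C26-bearing replicate 3 (camera adjusted p = 0.0136) and without control replicate 1 (0.0402), and the liver list without control replicate 3 (0.0410).

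The let-7 list had 7 of 9 members above 0 and a median of 0.62 (camera adjusted p = 0.125). Within the libraries with little miR-5119 its adjusted p was 0.0365. The muscle-wasting-linked list had 5 of 8 above 0 (median 0.80, adjusted p = 0.505), and miR-181a-5p, one of its members, had a log2 fold change of -1.61 (SE 0.566). The myeloid and inflammation-induced list had 5 of 8 above 0 (median 0.17, adjusted p = 0.605), with miR-142a-3p at 1.98 (SE 0.924), miR-146a-5p at -1.18 (SE 0.600) and miR-223-3p at 2.27 (SE 1.75). With each library left out in turn, miR-146a-5p ran from -1.52 to -0.17 and miR-223-3p from 1.45 to 4.08. The platelet and endothelial list had 5 of 7 above 0 (median 0.38, adjusted p = 0.456), with miR-126a-5p at 3.23 (SE 1.39), miR-126a-3p at 0.37 (SE 0.374), miR-191-5p at 0.75 (SE 0.398) and miR-199a-3p at 0.77 (SE 0.767). The energy metabolism and hypoxia list had 2 of 4 above 0 (median 0.06, adjusted p = 0.990), with miR-103-3p at 1.00 (SE 0.650) and miR-29a-3p at 0.16 (SE 0.520). The miR-17/92 list had a median of -0.06 and a mean of 0.54 (adjusted p = 0.710), with miR-93-5p at 1.56 (SE 0.731) and miR-25-3p at -0.37 (SE 0.537). The list of pancreas, gut and neural miRNAs had a median of 0.00 (adjusted p = 0.711), with miR-7a-5p at 1.36 (SE 0.553) and miR-128-3p at -0.69 (SE 0.795). The 3 tested members of the Dlk1-Dio3 cluster, miR-127-3p, miR-434-5p and miR-541-5p, lay below 0 (median -0.59, adjusted p = 0.605). The lymphocyte and miR-34 lists had fewer than 3 members tested in the main fit. Within the libraries with little miR-5119 the lymphocyte list had 3 members tested and was lower (median -1.75, camera adjusted p = 0.0436). In the other settings that tested it the direction was also down, with camera adjusted p from 0.258 to 0.469. miR-8101, in none of the lists, had a log2 fold change of 4.95 (SE 1.74) with counts of 9, 20, 177, 7, 341 and 0 in C26-bearing replicates and 6, 4, 10 and 2 in controls.

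Red cell miRNAs did not separate the groups. The erythrocyte list had 2 of 6 tested members above 0 and 4 below (median -0.15, camera adjusted p = 0.605). miR-451a had a log2 fold change of -0.28 (SE 0.462), miR-486a-5p of -0.03 (SE 1.10) and miR-144-3p of -1.13 (SE 0.542). The haemolysis index, log2 of the ratio of miR-451a to miR-23a-3p, was 5.55 ± 1.84 (SD, n = 6) in C26-bearing mice and 7.05 ± 1.22 (SD, n = 4) in controls, a difference of -1.50 (exact permutation p = 0.186, adjusted over 4 library measures 0.371). Without C26-bearing replicate 5 the difference was -2.08 (exact permutation p = 0.0476). The index also varied with the miR-5119 parts. It ran from 3.53 to 6.40 in the libraries with much miR-5119 and from 6.23 to 8.49 in those with little.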

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

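The tests of depth, of sheet order and of tumour bearing below were chosen after the miR-5119 shares had been seen, and the counts of other splits had been computed before their criteria were written down. A sample far from the others of its group appeared in 6 of 114 groups of values examined, and chance alone gives about 5.7.

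Control replicate 4 stood apart from the other 3 controls in 4 measures. Its miR-5119 share was 46.1%, where the others held 0.0968% to 0.819%, and this was also the share of its most abundant miRNA, against 24.8% to 25.5%. Its haemolysis index was 5.24, against 7.41 to 7.82. Its miR-8101 level was 8.57 log2 CPM, against 6.45 to 6.59, from 2 counts in a library of 7962. The level of miR-200a-3p in control replicate 1 was 9.20 log2 CPM, against 8.57 to 8.65 in the others. The level of miR-103-3p in C26-bearing replicate 4 was 7.09 log2 CPM, against 8.86 to 9.84, from 1 count.

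The high share of miR-5119 in 5 of 10 plasma libraries crossed the groups, with 4 of 6 C26-bearing libraries and 1 of 4 controls above 20%. Low total depth alone is argued against, since 2 of the 5 libraries with over 50000 counts have 95% Wilson intervals above 20%. These totals include miR-5119 itself, 29359 of 76376 counts in C26-bearing replicate 2 and 38790 of 66088 in replicate 3. The test therefore cannot decide whether a low yield of other miRNAs is the cause. The 5 rich libraries have consecutive sheet numbers, 18 to 22, which 6 of 252 placements of 5 libraries among the 10 numbers give (exact p = 0.0238), so a batch of handling or library preparation in sheet order is a candidate explanation, found and tested on the same data. Tumour bearing as a biological explanation stays open, since the part and the group were associated with Fisher's exact p = 0.524, and 4 against 6 libraries are too few to exclude it. Controls have numbers 15 to 18 and C26-bearing libraries 19 to 24, so sheet order separates the groups completely.

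For the comparison of plasma groups, chance cannot be excluded for the number of gene lists or for the TMV set. The count of 0 miRNAs gives no test of chance, since all 100 of the 100 splits of the 10 libraries into 6 and 4 give at least 0 by construction, and the highest other split gave 30. That split set C26-bearing replicate 6 and control replicates 1 to 3 against the rest, close to the miR-5119 parts, which points to a structure of the libraries other than the groups. At least 1 gene list passed in 35 of the 100 splits, and the highest other split had 3. For the TMV set, 49 of the 100 splits gave a camera p as small as 0.458, and the smallest p of the other splits was 0.0118.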

How the results depend on the processing

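Chosen after seeing the data were leaving miR-5119 out of the table, a term for the miR-5119 part, each part alone, and leaving out the 2 libraries under 10000 counts; other alternatives were planned. Where no cause is given below, the cause was not tested. The edgeR count of 0 miRNAs in plasma (15 at an unadjusted p under 0.05) stayed at 0 with RLE, upper quartile and total-count scaling, with the 10 CPM filter (335 tested), without robust estimation, without both controls that carry 2 numbers, without miR-5119, within the part with little miR-5119 and without the libraries under 10000 counts. It was 4 without a filter, 4 with DESeq2, 17 with limma voom, 2 with the part as a term and 1 within the part with much miR-5119, where it rests on 1 control, and it ranged from 0 to 1 with each library left out. RLE scaling moved the median log2 fold change over all miRNAs from 0.01 to 0.19, so values under it are relative to that shift. Replicate numbers did not pair the libraries (correlations of same-numbered deviations -0.37, -0.29, -0.30 and 0.16), and with a replicate block the count stayed 0, lists past the threshold went from 1 to 0, the epithelial list had an adjusted p of 0.118 and the TMV set had p = 0.755 with the direction down. The number of lists past the threshold was 0 with an estimated correlation, 0 with fry, 2 with total-count scaling, 2 with the part as a term, 4 within little miR-5119, 0 within much, 0 without the libraries under 10000 counts, and 0 to 2 with each library left out. For the epithelial list the adjusted p was 0.383 with an estimated correlation, 0.0636 with fry, 0.0737 with the part as a term, 0.441 within little miR-5119, 0.115 without the libraries under 10000 counts and 0.0216 to 0.213 with each library left out. The direction of the list was down in all of these. The muscle list passed at 0.0415 with total-count scaling, 0.0136 without C26-bearing replicate 3 and 0.0402 without control replicate 1, and the liver list at 0.0410 without control replicate 3. The camera p of the TMV set was 0.0478 (up) without C26-bearing replicate 3, 0.865 (down) without C26-bearing replicate 6, the ends of the range with each library left out, and 0.0402 (up) with 100 miRNAs of the 130 tested. Detected TMV miRNAs numbered 343 at 1 count and 106 at 50 counts, by construction of the minimum, and 170 to 184 with each library left out. Shared abundant miRNAs numbered 8 of 20 and 65 of 100, by construction of the list size. The haemolysis difference kept its sign, from -2.10 to -1.09 with each library left out, and passed an exact permutation test at -2.08 without C26-bearing replicate 5. Among 1251 alternative values of 52 named miRNAs, 74 changed sign, 57 of them with both values within 1 SE of 0, and 29 miRNAs kept their sign in every setting. Of 239 alternative list values 17 changed sign with no call on either side. The sign changes in which the value as reported, the alternative or both lay beyond 1 SE of 0 were, with the part as a term, miR-101b-3p -0.58, miR-16-5p -0.10, miR-17-5p -0.62 and miR-223-3p -0.95; within little miR-5119, miR-101b-3p -0.99, miR-106b-3p 0.68, miR-126a-5p -0.41, miR-143-3p -0.77, miR-16-5p -0.26, miR-29a-3p -0.79, miR-486a-5p 1.09 and miR-99b-5p 0.64; within much (1 control), miR-192-5p 0.22, miR-199a-3p -0.23 and miR-99a-5p 0.47; and with a library left out, miR-140-3p from -0.52 to 0.70 (control replicate 4) and miR-434-5p from -1.04 (control replicate 2) to 0.92 (control replicate 1). The 16.5-fold range of depth limits miRNAs of low level, since 0 counts in the shallowest plasma library allow up to 377 CPM.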

Other observations

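The test of TMV-enriched miRNAs was set before its result was seen. The tests of the muscle to liver ratio and of single TMV libraries, and the choice of miR-31-5p and miR-34c-5p, came after the values had been seen.

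miR-31-5p and miR-34c-5p were present in TMVs and near the detection floor in plasma of both groups. miR-31-5p, an epithelial miRNA, held 0.611% ± 0.156 (SD, n = 3) of TMV counts, with 1148, 639 and 820 counts. In plasma it had 8 counts of 231670 over the 6 C26-bearing libraries (exact 95% interval 0.00149% to 0.00680%) and 9 of 321126 over the 4 controls (0.00128% to 0.00532%). miR-34c-5p held 0.216% ± 0.0461 of TMV counts and had 1 count in each plasma group. The intervals cover counting error only.

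The ratio of muscle-enriched to liver miRNAs within a library was higher in most C26-bearing plasma libraries. Per library the counts of the muscle list divided by those of the liver list gave 1.42, 0.625, 1.84, 0.803, 10.3 and 0.342 in C26-bearing replicates 1 to 6 and 0.0588, 0.0579, 0.0802 and 0.593 in control replicates 1 to 4. The mean log2 ratio was 0.37 ± 1.70 (SD, n = 6) against -3.15 ± 1.61 (SD, n = 4), and 5 of 6 C26-bearing libraries lay above all controls. The exact permutation p of 0.0143 takes no account that these lists were chosen because they had moved apart. Over all 66 pairs of the 12 lists, 72 of 210 splits of the libraries held a pair with as small a p (0.343, exact permutation), so chance in the choice of these 2 lists is not excluded. The tests of other explanations ran on the same chosen lists and decide nothing: the exact permutation p was 0.02 with groups exchanged only within the miR-5119 parts, of which the one with much holds 1 control, 0.0238 without miR-1a-3p and miR-122-5p, and 0.0810 for liver miRNAs against all others. For muscle miRNAs against all others it was 0.114, with 3 of 6 C26-bearing libraries above all controls. The difference in mean log2 muscle to liver ratio was 4.86 within the libraries with little miR-5119. Within those with much, which hold 1 control, it was 0.85. Sheet numbers separate the groups, so an effect of handling is open too, as is tumour bearing.

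Single TMV libraries held muscle or red cell miRNAs far above the other 2. miR-1a-3p had 1014 counts in TMV replicate 2 against 118 and 110, a share 12.6 times that of the others, and miR-451a had 866 in replicate 3 against 68 and 78, 9.0 times. Carry-over of plasma libraries is argued against in both, 2 of 2, because miR-122-5p had 33 and 64 counts (exact Poisson upper bounds 46.3 and 81.7) where the lowest plasma ratio would need 91.5 and 130. Carry-over of muscle or blood RNA from outside these libraries stays open: miR-133a-3p had 21.2 times and miR-486a-5p 2.54 times the share in the other libraries, but miR-206-3p only 1.47 times in replicate 2 and miR-16-5p 1.65 times in replicate 3, where miR-144-3p had 2 counts. No biological explanation was tested, since the TMVs form 1 group.

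If tumour vesicles added to plasma, miRNAs enriched in TMVs may be expected higher in C26-bearing mice. For each of the 6 choices of 2 controls, the 30 miRNAs most enriched in TMVs over those controls were tested in C26-bearing plasma against the other controls. In 0 of the 6 choices was the set higher at a camera p under 0.05; p ranged from 0.127 to 0.984, and the camera direction, which is relative to the other miRNAs, was up in 3 of 6. The mean log2 fold change of the set was above 0 in 6 of 6 (0.0221 to 0.396), and its median ran from -0.18 to 0.62. These data do not decide the hypothesis of tumour vesicles added to plasma.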
